A study of Rattus norvegicus with 9 samples.

How the data were processed

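Per the labels, myocytes of 2-day-old rats received 2 siRNAs per target, each at 25 nM, and poly-A RNA was sequenced from 9 libraries, 3 per group, by a low-input BGISEQ-500 protocol. With 2 genes targeted, the Llgl1/2 group may have received more siRNA in total than the Yap group. Total siRNA load therefore cannot be told apart from the target. The deposited table gives FPKM, made by the authors for each gene and library and rounded to 2 decimals. The submitters' processing notes name Bowtie2, HISAT and the rn6 genome without a version or a role, and no counting tool or annotation is named. The table has no counts. A column named as if it covered all libraries equals Llgl1/2 library 2 in all 14636 rows, so it was not used.

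All values below were computed from the FPKM table. Gene names came from the file, and 31 symbols that had been read as dates or were missing were looked up by gene ID in a GRCr8 gene table, which gave a symbol for 29. That table held 14516 of the IDs. It is a different assembly from rn6, so no coordinates were used. A symbol shared by several genes occurs in 4 rows, and 507 genes were at 0 in every library. The number of genes at or above 1 FPKM was 10449 to 10565 per library, and the 10 highest genes held 8.33% to 10.1% of the FPKM sum. Relative depth was estimated from genes whose values in several libraries match the same small number of reads. Llgl1/2 library 1 was the reference, and the other libraries shared only 3 to 12 such genes with it. Only ratios within 0.4 on the log2 scale were kept, which holds the estimate near 1, so it is rough. The median standard error of a log2 change against the control was 0.106.

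The rules of grouping, testing, naming genes and listing genes were fixed before the data were examined. FPKM values were tested in limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with moderated variances that follow the mean level and are robust to outlying genes. Genes with at least 1 FPKM in at least 3 libraries were kept, which removed 3847 genes and left 10789. All 9 libraries entered a single fit with a mean per group and 6 residual degrees of freedom. Adjusted p-values follow Benjamini and Hochberg over all tested genes, with a threshold of 0.05. Log2 changes and their standard errors come from that fit, and folds are ratios of mean FPKM. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The code was tested on simulated data with 200 changed genes among 10789, in 5 simulations per comparison. Changes of 0.5, 1 and 2 on the log2 scale were found in 61.1%, 92.6% and 99.4% of cases for Llgl1/2 siRNA, 60.3%, 93.9% and 99.7% for Yap siRNA, and 57.5%, 97.0% and 99.7% in the direct comparison. False calls made up 3.56%, 5.12% and 5.39%. The simulated noise was drawn independently for each gene and library. These rates check the code and do not give the share of false calls in the real data.

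Gene lists and cell type marker lists were tested with camera in limma at its preset correlation between genes of 0.01, adjusted over the 36 lists with at least 3 tested members. The lists covered YAP/TAZ targets, Hippo components, apicobasal and planar cell polarity, the G1/S and G2/M phases, sarcomere, fetal and stress genes, calcium handling, oxidative phosphorylation, fatty acid oxidation, glycolysis, junctions, focal adhesion and SRF/MRTF targets, extracellular matrix, TGF-beta, Wnt, Notch, interferon, NF-kB, stress response, p53, antioxidant, sterol synthesis, hypoxia, growth factor, apoptosis, cardiac transcription factor and immediate early genes. Marker lists covered fibroblasts, endothelium, smooth muscle and pericytes, leukocytes, epicardium, erythroid and neural cells and working cardiomyocytes. Llgl1, Llgl2 and Yap1 were left out of every list. A count "adjusted over the list alone" applies the gene threshold to p-values adjusted within that list. Alternatives were an estimated correlation and the fry test. Genes named are the targets, the 12 steepest rises and falls of each comparison with the control and 6 in the direct comparison (mean of at least 5 FPKM, no overlap between groups), and up to 4 members per list by smallest p, or 2 where none passed.

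Overlap between both knockdowns was set beside independent lists and 100 simulations of unchanged groups with shared controls. Alternatives set beforehand were a pseudocount of 0.1, no filter, quantile normalization, only the 6 libraries compared, replicate number as a factor, an adjusted p of 0.01, a log2 change of at least 1, and leaving out each library. Alternatives chosen after the data were seen were median-ratio scaling, a filter at 10 FPKM in 3 libraries and gene ontology process terms of 15 to 200 tested genes. Alternatives that need counts were not run.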

Results

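The data are RNA-seq profiles of primary cardiac myocytes from 2-day-old Sprague Dawley rats. The cells were freed with a heart dissociation kit, separated on a Percoll gradient and cultured in medium with 15% serum, then transfected after 16 h with siRNAs and collected 48 h later. Llgl1 and Llgl2 encode the mammalian homologs of the fly protein lethal giant larvae, a basolateral cell polarity protein, and Yap1 encodes YAP, the transcriptional coactivator that the Hippo kinase pathway holds in check. There were 3 groups of 3 libraries: siRNA against both Llgl1 and Llgl2 (Llgl1/2 siRNA), siRNA against Yap, and universal negative control siRNA. The deposited values are FPKM for 14636 genes. Their sum per library ran from 572884 to 620119, and the number of genes above 0 from 12703 to 12831. Read totals are not part of these values. From 3 to 12 usable genes per library, among 146 with few reads, relative depth was estimated against Llgl1/2 library 1. It was 0.99 to 1.00 for Llgl1/2 siRNA, 1.10 for the controls and 1.06 to 1.10 for Yap siRNA. This says nothing of the absolute depth. Libraries of the same group correlated at 0.990 to 0.994 across genes (Pearson, log2 scale) and libraries of different groups at 0.957 to 0.979. Genes are not independent replicates. Principal component 1 held 46.5% of the variance and set the Yap siRNA libraries apart, and component 2 held 32.2% and set the Llgl1/2 siRNA libraries apart from the controls. The labels do not say that replicates were separate cultures, so all p-values measure only the spread between these libraries, which may be technical.

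The targeted genes came first, as a check of the labels. Llgl1 (gene ID 54265) averaged 12.1 ± 0.225 FPKM (SD, n = 3) in the control libraries and 4.72 ± 0.0608 in the Llgl1/2 siRNA libraries, a mean ratio of 0.389. Llgl2 (gene ID 360661) averaged 13.6 ± 1.46 in the controls and 7.15 ± 0.576 after Llgl1/2 siRNA, a ratio of 0.525, so more than 50% of the control level was left. Yap1 (gene ID 363014) averaged 59.7 ± 4.03 in the controls and 5.44 ± 0.879 after Yap siRNA, a ratio of 0.0911. In limma's test Llgl1 fell (adjusted p = 3.9e-06) and Llgl2 fell by 0.84 ± 0.13 (SE) on the log2 scale (adjusted p = 0.00025) after Llgl1/2 siRNA, and Yap1 fell by 3.24 ± 0.11 (adjusted p = 1.7e-10) after Yap siRNA. Each was lower in all 3 treated libraries than in any control library. The untargeted genes were also read. Yap1 averaged 52.4 ± 5.28 FPKM after Llgl1/2 siRNA, with overlapping libraries and a log2 change of -0.19 ± 0.11 (limma, adjusted p = 0.18). After Yap siRNA, Llgl1 averaged 8.84 ± 1.48 and Llgl2 9.60 ± 2.10 FPKM, and limma placed both below the controls, by -0.43 ± 0.11 (adjusted p = 0.0064) and -0.48 ± 0.13 (adjusted p = 0.0086).

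**Figure D1:**
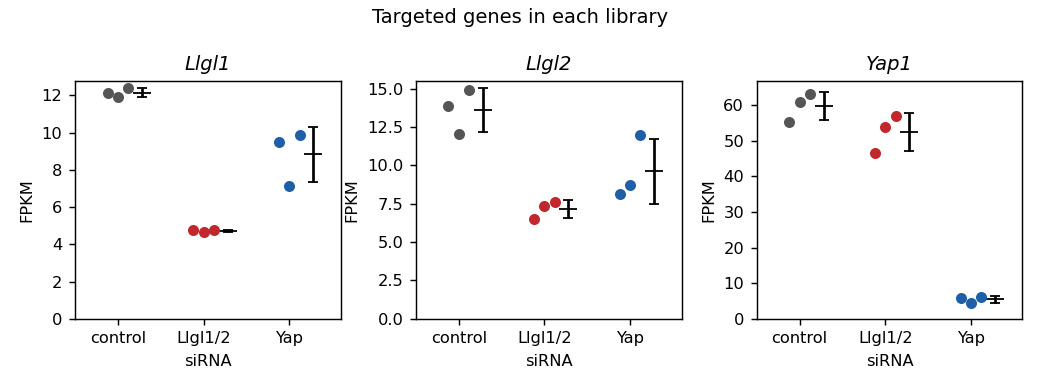
FPKM of Llgl1, Llgl2 and Yap1 in each of the 9 libraries, with each group's mean and SD (n = 3) as a bar beside the points. Llgl1 and Llgl2 averaged 4.72 and 7.15 FPKM after Llgl1/2 siRNA against 12.1 and 13.6 in the controls, and Yap1 5.44 after Yap siRNA against 59.7.

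The first comparison asked which genes differ after siRNA against both Llgl genes. Inflammatory and interferon-induced genes, endothelial markers, cell cycle genes and sterol synthesis genes fell, and genes of the sarcomere, of fatty acid oxidation and of the cardiac transcription factor group rose. These are list calls at camera's preset correlation, and none passed with an estimated correlation (adjusted p = 0.41 to 0.43). The chemokine genes Cxcl6 and Cxcl1 went from 53 ± 15.9 to 9.25 ± 2.23 FPKM and from 404 ± 91.5 to 100 ± 5.97 (SD, n = 3 per group), and Nos2, the inducible nitric oxide synthase, from 12.5 ± 1.06 to 2.03 ± 0.27. Cacna1g, which encodes a T-type calcium channel subunit, rose 4.10-fold from 13.1 ± 0.958 to 53.8 ± 1.66 FPKM. In all, 4338 of 10789 tested genes passed limma's threshold of an adjusted p of 0.05, 2380 higher and 1958 lower. The split depends on the scaling: median-ratio scaling, chosen after seeing the data, gave 2104 higher and 2162 lower. Most of these changes were small: 95 of the higher and 165 of the lower genes moved by at least 1 on the log2 scale.

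Of the 25 tested genes of the NF-kB inflammatory list, 22 fell and 1 rose after Llgl1/2 siRNA, with a median log2 change of -1.15 (camera, adjusted p = 2.2e-16, and adjusted p = 0.41 with an estimated correlation). Adjusted over the list alone the counts were again 22 and 1. Cxcl3 fell by 1.89 ± 0.09 (SE) on the log2 scale, the complement gene C3 fell by 1.82 ± 0.10, and Csf1, the macrophage growth factor gene, fell by 1.18 ± 0.07. The exception was the chemokine gene Ccl20, which rose 3.29-fold from 7.97 ± 1.07 to 26.2 ± 2.14 FPKM (SD, n = 3). Among interferon-stimulated genes 21 of 27 fell and none rose (median -0.63, camera, adjusted p = 3.4e-11, and adjusted p = 0.41 with an estimated correlation), and 22 fell and 1 rose when adjusted over the list alone. Rsad2, an antiviral effector, fell by 1.53 ± 0.11 and Gbp2, a guanylate-binding protein gene, fell by 1.67 ± 0.13. Other genes among the steepest falls were Slpi, a leukocyte protease inhibitor (-2.44 ± 0.14), the colony-stimulating factor genes Csf3 (-2.26 ± 0.28) and Csf2 (-2.02 ± 0.15), the chemokine genes Cxcl10 (-2.01 ± 0.11) and Ccl12 (-1.91 ± 0.30), and the metallothionein gene Mt2A (-2.34 ± 0.11). All of these had limma adjusted p-values of 0.0020 or less.

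Markers of other cell types moved beside the inflammatory genes. Of 14 endothelial markers 13 fell and none rose (median log2 change -1.04, camera, adjusted p = 2.0e-10, and adjusted p = 0.41 with an estimated correlation), with the same counts when adjusted over the list alone. Eng went from 279 ± 27.1 to 110 ± 2.73 FPKM (SD, n = 3) and Cdh5, the vascular endothelial cadherin gene, from 92.7 ± 9.32 to 42.3 ± 0.419. Selp, an adhesion molecule of activated endothelium and platelets, went from 148 ± 20.5 to 32.7 ± 2.68. Of 15 macrophage and other leukocyte markers 8 fell and none rose (median -0.46, camera, adjusted p = 0.00092, and adjusted p = 0.43 with an estimated correlation), again 8 when adjusted over the list alone. Cd14 was at -1.19 ± 0.15 (SE). Cardiac fibroblast markers went both ways: of 13, 3 fell and 2 rose, with and without adjustment over the list alone, with Lum at -1.14 ± 0.13, Dcn at -0.98 ± 0.13 and Thy1 at 0.48 ± 0.12 (camera, adjusted p = 0.074). Of 13 smooth muscle and pericyte markers 5 rose and 2 fell (camera, adjusted p = 0.48), among them Acta2, which fell by 0.98 ± 0.08, and Cnn1, which rose by 0.53 ± 0.09. Krt8 and Krt18, keratin genes on the epicardial list, rose by 1.56 ± 0.19 and 1.01 ± 0.18, and that list had 3 of 7 higher (camera, adjusted p = 0.32). Of 4 erythroid markers none passed limma's test at an adjusted p of 0.05, and Hbb-b1 was at -0.26 ± 0.17. The neural and Schwann list, with 2 tested markers, was too short to test.

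Proliferation genes fell after Llgl1/2 siRNA. The libraries also hold markers of other cell types, so these falls cannot be assigned to the myocytes. In the G2/M and mitosis list 22 of 23 genes fell (median log2 change -0.56, camera, adjusted p = 1.0e-10, and adjusted p = 0.41 with an estimated correlation), with the same count when adjusted over the list alone. Cdk1, the mitotic kinase gene, went from 72.4 ± 3.47 to 41.2 ± 3.33 FPKM (SD, n = 3) and Plk1 from 35.8 ± 2.51 to 21.0 ± 1.92. In the G1/S and DNA replication list 14 of 25 fell and 1 rose (median -0.34, camera, adjusted p = 1.4e-05, and adjusted p = 0.41 with an estimated correlation), the same counts as when adjusted over the list alone. Ccnd1, the cyclin D1 gene, fell by 1.10 ± 0.09 (SE) and Rrm2, a ribonucleotide reductase subunit gene, fell by 0.98 ± 0.09. Sterol synthesis genes fell in 19 of 24 cases and rose in none (median -0.51, camera, adjusted p = 4.0e-08, and adjusted p = 0.41 with an estimated correlation), also 19 when adjusted over the list alone. Idi1, an isomerase of the isoprenoid pathway, fell by 0.85 ± 0.09.

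Metabolic, contractile and cardiac regulatory genes rose. Fatty acid oxidation genes rose in 21 of 29 cases and fell in 2 (median log2 change 0.38, camera, adjusted p = 1.4e-05, and adjusted p = 0.41 with an estimated correlation), or 22 and 2 when adjusted over the list alone. Cd36, the fatty acid transporter gene, rose from 73.4 ± 4.58 to 134 ± 5.42 FPKM (SD, n = 3) and Cpt2, of the mitochondrial carnitine shuttle, from 27.3 ± 1.93 to 53 ± 3.32, while Angptl4, an inhibitor of lipoprotein lipase, fell by 2.17 ± 0.12 (SE). Oxidative phosphorylation genes rose in 16 of 29 cases and fell in none (median 0.24, camera, adjusted p = 0.00014, and adjusted p = 0.43 with an estimated correlation), or 17 when adjusted over the list alone. Cox5b was at 0.44 ± 0.09. Cardiac transcription factor genes rose in 16 of 25 cases and fell in none (median 0.40, camera, adjusted p = 7.9e-05, and adjusted p = 0.41 with an estimated correlation), or 18 when adjusted over the list alone. Gata6 was at 0.62 ± 0.07 and Tbx5 at 0.89 ± 0.12. In the sarcomere list 15 of 23 rose and 1 fell (median 0.36, camera, adjusted p = 0.00049, and adjusted p = 0.43 with an estimated correlation), with the same counts when adjusted over the list alone. The thick filament genes Mybpc3 and Myom2 rose from 247 ± 30.4 to 396 ± 12 and from 87.8 ± 14.4 to 155 ± 5.69 FPKM. Of 14 working cardiomyocyte markers 9 rose and none fell (median 0.41, camera, adjusted p = 0.0014, and adjusted p = 0.41 with an estimated correlation), or 10 when adjusted over the list alone. Calcium handling and ion channel genes rose in 14 of 25 cases and fell in 3 (median 0.35, camera, adjusted p = 0.0080, and adjusted p = 0.54 with an estimated correlation), with the same counts when adjusted over the list alone. Cacnb2, a calcium channel subunit gene, rose by 0.63 ± 0.08 and Kcnd2, a potassium channel gene, fell by 0.71 ± 0.13.

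Matrix, adhesion and YAP-related lists also fell. Extracellular matrix genes fell in 11 of 22 cases and rose in none (median log2 change -0.24, camera, adjusted p = 0.00017, and adjusted p = 0.41 with an estimated correlation), also 11 when adjusted over the list alone, with Eln, the elastin gene, down from 70.3 ± 2.80 to 33.4 ± 0.239 FPKM (SD, n = 3). Among YAP/TAZ target genes 10 of 19 fell and 1 rose (median -0.22, camera, adjusted p = 0.0012, and adjusted p = 0.41 with an estimated correlation), or 11 and 1 when adjusted over the list alone. Igfbp3 fell by 1.97 ± 0.23 (SE), Axl fell by 0.90 ± 0.12 and Ctgf, the connective tissue growth factor gene, fell by 0.50 ± 0.10. In the focal adhesion and SRF/MRTF cytoskeletal list 13 of 26 fell and 5 rose (median -0.20, camera, adjusted p = 0.0071, and adjusted p = 0.43 with an estimated correlation), or 13 and 6 when adjusted over the list alone. Itgb1, the integrin beta subunit gene, went from 759 ± 20.4 to 345 ± 5.75 FPKM. TGF-beta response genes fell in 9 of 20 cases and rose in 3 (median -0.28, camera, adjusted p = 0.0053, and adjusted p = 0.43 with an estimated correlation), with the same counts when adjusted over the list alone. Unfolded protein and integrated stress response genes fell in 10 of 24 cases and rose in 3 (median -0.23, camera, adjusted p = 0.022, and adjusted p = 0.41 with an estimated correlation), or 11 and 3 when adjusted over the list alone. The chaperone gene Hspa5 was at -0.61 ± 0.07. Apicobasal polarity genes, from which Llgl1 and Llgl2 had been taken out, rose in 6 of 18 cases and fell in none (median 0.19, camera, adjusted p = 0.047, and adjusted p = 0.41 with an estimated correlation), with the same counts when adjusted over the list alone. Crb3, a Crumbs complex gene, rose from 1.02 ± 0.148 to 3.20 ± 0.629 FPKM and Patj by 0.70 ± 0.13. That list's call was lost with a pseudocount of 0.1 (camera, adjusted p = 0.055), no filter (0.058), quantile normalization (0.068) or a filter at 10 FPKM (0.34), and without Llgl1/2 library 2 (0.072) or 3 (0.069) or control library 1 (0.075) or 3 (0.062).

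The other lists did not pass camera's threshold after Llgl1/2 siRNA, though some did in other settings. Planar cell polarity passed with median-ratio scaling (camera, adjusted p = 0.047) and without Llgl1/2 library 2 (0.043), junctions without Llgl1/2 library 1 (0.043) or control library 2 (0.0498), and fibroblast markers without Llgl1/2 library 1 (0.039) or control library 3 (0.021). Planar cell polarity genes had 6 of 15 higher and 1 lower (camera, adjusted p = 0.059), junction genes 11 of 18 higher and 2 lower (adjusted p = 0.074), p53 targets 9 of 22 higher and 4 lower (adjusted p = 0.15) and growth factor genes 5 of 22 higher and 8 lower (adjusted p = 0.10). Apoptosis regulators had 3 of 24 higher and 8 lower (camera, adjusted p = 0.16), immediate early genes 3 of 22 higher and 5 lower (adjusted p = 0.165), hypoxia genes 6 of 18 higher and 7 lower (adjusted p = 0.26) and glycolysis genes 7 of 22 higher and 6 lower (adjusted p = 0.42). Fetal and stress genes of the myocyte had 4 of 13 higher and 3 lower (camera, adjusted p = 0.565), Notch genes 2 of 10 higher and 3 lower (adjusted p = 0.59) and antioxidant genes 9 of 25 higher and 6 lower (adjusted p = 0.70). Wnt targets had 4 of 13 higher and 5 lower (camera, adjusted p = 0.60) and Hippo pathway components 3 of 23 higher and 4 lower (adjusted p = 0.75), and in both the median, 0.04 and 0.01, had the opposite sign to the mean, -0.09 and -0.02, and to the test. Adjusted over the list alone, these lists differed by at most 2 genes in either direction from the counts given. Within them Tp53inp1, a p53-induced stress gene, rose by 1.73 ± 0.14 (SE), the natriuretic peptide gene Nppb fell by 0.83 ± 0.10, and the small heat shock protein gene Cryab rose by 0.91 ± 0.10. In total 19 of 36 lists passed, 7 higher and 12 lower, and none passed with an estimated correlation.

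**Figure D2:**
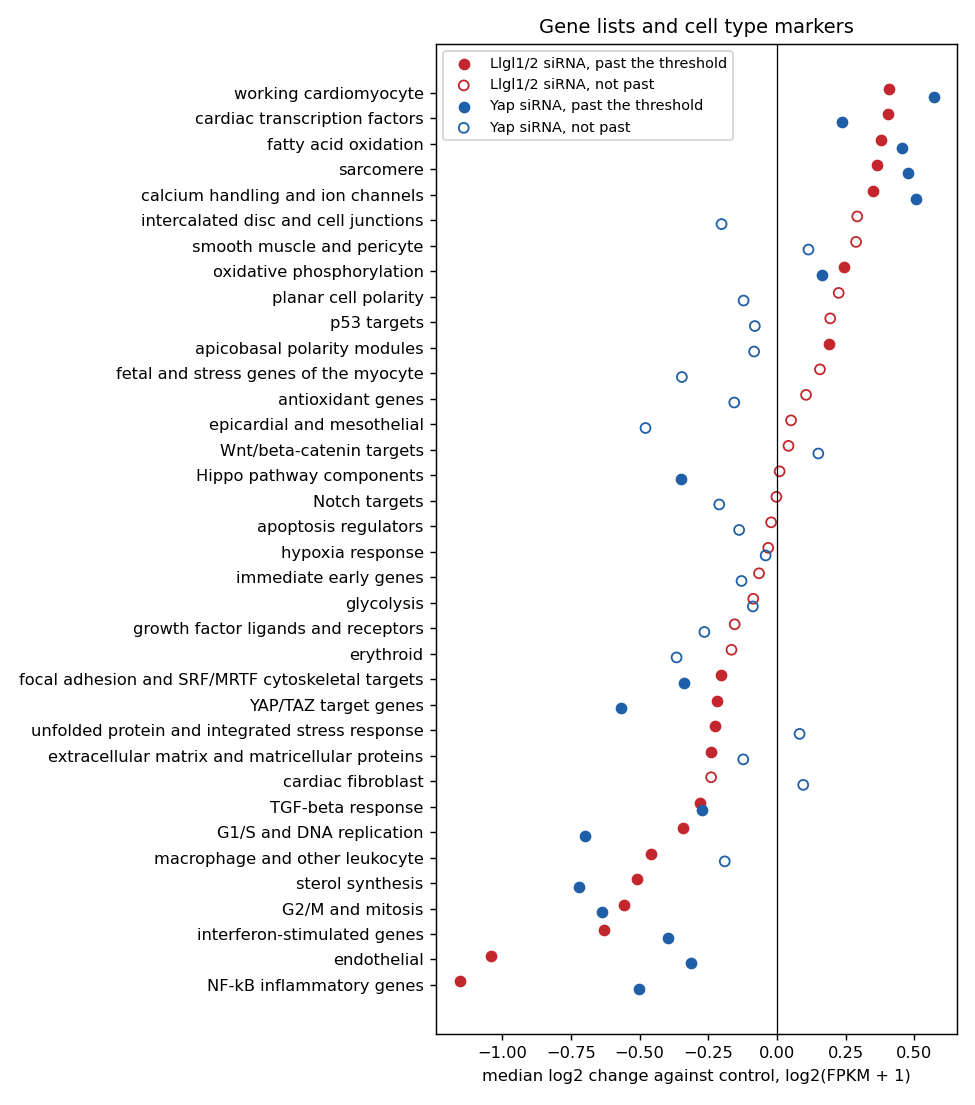
Median log2 change of each gene list after Llgl1/2 siRNA and after Yap siRNA against the control, on the log2(FPKM + 1) scale, with filled points for lists past camera's threshold with its preset correlation. The NF-kB list had medians of -1.15 and -0.50, and fatty acid oxidation 0.38 and 0.45.

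The second comparison asked which genes differ after Yap siRNA. Cell cycle genes, YAP/TAZ targets, sterol synthesis genes and cytoskeletal genes fell, and genes of fatty acid oxidation and calcium handling and many sarcomere genes rose. Here too the calls hold at camera's preset correlation, and none passed with an estimated correlation (adjusted p = 0.48 to 0.59). Acta2, the smooth muscle actin gene, went from 2353 ± 101 to 427 ± 25.4 FPKM (SD, n = 3) and Acta1, the skeletal muscle actin gene, from 535 ± 21.1 to 132 ± 16.9. Lrrc10, a heart-specific leucine-rich repeat protein gene, rose 6.21-fold from 19.0 ± 1.24 to 118 ± 7.05, and Mb, the myoglobin gene, 4.23-fold from 126 ± 13.4 to 531 ± 14.8. In all, 5181 of 10789 tested genes passed limma's threshold, 2217 higher and 2964 lower. The surplus of lower genes was far smaller with median-ratio scaling (2528 higher and 2612 lower) and with quantile normalization (2460 and 2638). Of these, 260 of the higher and 187 of the lower genes moved by at least 1 on the log2 scale.

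Among the steepest changes after Yap siRNA, Igfbp5, which encodes an insulin-like growth factor binding protein, rose 27.1-fold from 1.35 ± 0.716 to 36.7 ± 4.69 FPKM (SD, n = 3), and it also rose after Llgl1/2 siRNA, 6.86-fold to 9.29 ± 3.95. The secreted protein genes Reg3b, Pla2g2a and Hamp, the gene for the iron hormone hepcidin, rose by 2.96 ± 0.13 (SE), 2.54 ± 0.11 and 2.24 ± 0.15 on the log2 scale. Sphkap, a kinase anchoring protein gene, rose by 2.43 ± 0.13 and Cygb, the cytoglobin gene, by 2.05 ± 0.15, and both also rose after Llgl1/2 siRNA, by 1.94 ± 0.13 and 1.66 ± 0.15. Falls included Krt18 at -2.46 ± 0.18, Tril, a Toll-like receptor accessory gene, at -2.54 ± 0.11, the growth factor receptor gene Fgfr2 at -2.32 ± 0.12, the muscle acetylcholine receptor gene Chrna1 at -2.16 ± 0.19 and the glutamate transporter gene Slc1a3 at -2.15 ± 0.08. All had limma adjusted p-values of 2.1e-06 or less, except Igfbp5 (1.9e-05 after Yap siRNA and 0.0013 after Llgl1/2 siRNA) and the Llgl1/2 siRNA value of Cygb (2.6e-06). Myl6l, a near-copy of the myosin light chain gene Myl6, was listed at 0 in the 6 control and Llgl1/2 siRNA libraries and at 212, 519 and 250 FPKM in the Yap siRNA libraries, and its value is uncertain because the pair can share reads. The same holds for the ribosomal genes Rn5s (3.03 ± 0.37) and Rn5-8s (2.57 ± 0.18), whose transcripts a poly-A library should not hold, and for Rpl37a (-2.36 ± 0.27), a gene of a family with many pseudogene copies.

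All 23 G2/M and mitosis genes fell after Yap siRNA (median log2 change -0.64, camera, adjusted p = 8.9e-09, and adjusted p = 0.48 with an estimated correlation), also 23 when adjusted over the list alone. Cdk1 went from 72.4 ± 3.47 to 33.1 ± 1.60 FPKM (SD, n = 3) and Ect2, a cytokinesis gene, from 14.4 ± 1.12 to 5.11 ± 0.487. As after Llgl1/2 siRNA, falls of cell cycle genes cannot be assigned to the myocytes. In the G1/S and DNA replication list 22 of 25 fell and 1 rose (median -0.70, camera, adjusted p = 1.2e-08, and adjusted p = 0.48 with an estimated correlation), or 23 and 1 when adjusted over the list alone. Rrm2 was at -1.55 ± 0.09 (SE) and Mcm6, of the replicative helicase, at -1.22 ± 0.08. Among YAP/TAZ targets 15 of 19 fell and 2 rose (median -0.57, camera, adjusted p = 8.1e-05, and adjusted p = 0.48 with an estimated correlation), with the same counts when adjusted over the list alone. Ctgf went from 691 ± 92.1 to 255 ± 22.9 FPKM, Amotl2 from 116 ± 1.44 to 57.0 ± 3.97 and Tgfb2 from 96.3 ± 9.54 to 29.7 ± 1.48. In the focal adhesion and SRF/MRTF cytoskeletal list 16 of 26 fell and 2 rose (median -0.34, camera, adjusted p = 9.2e-05, and adjusted p = 0.48 with an estimated correlation), with the same counts when adjusted over the list alone. Itgb1 was at -1.11 ± 0.07. TGF-beta response genes fell in 10 of 20 cases and rose in 1 (median -0.27, camera, adjusted p = 0.0041, and adjusted p = 0.59 with an estimated correlation), or 11 and 1 when adjusted over the list alone. Tgfb3 was at -1.90 ± 0.11. Sterol synthesis genes fell in 20 of 24 cases and rose in none (median -0.72, camera, adjusted p = 4.4e-07, and adjusted p = 0.48 with an estimated correlation), or 20 and 1 when adjusted over the list alone. Idi1 was at -1.13 ± 0.09. Hippo pathway components fell in 12 of 23 cases and rose in 4 (median -0.35, camera, adjusted p = 0.0498, and adjusted p = 0.59 with an estimated correlation), or 15 and 5 when adjusted over the list alone. The kinase gene Lats2 was at -1.12 ± 0.07. That call was lost with quantile normalization (camera, adjusted p = 0.057), a filter at 10 FPKM (0.059) or replicate number as a factor (0.052). It was also lost without control library 2 (0.051) or 3 (0.061) or Yap library 1 (0.078) or 3 (0.053).

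Metabolic and calcium handling genes of the myocyte rose after Yap siRNA. Fatty acid oxidation genes rose in 20 of 29 cases and fell in 1 (median log2 change 0.45, camera, adjusted p = 3.4e-08, and adjusted p = 0.48 with an estimated correlation), or 22 and 1 when adjusted over the list alone. Acsl1, which activates long-chain fatty acids, rose from 38.0 ± 3.20 to 100 ± 10.1 FPKM (SD, n = 3) and Etfdh, which feeds their electrons to the respiratory chain, from 76.6 ± 4.97 to 160 ± 6.71. Oxidative phosphorylation genes rose in 12 of 29 cases and fell in none (median 0.16, camera, adjusted p = 0.00046, and adjusted p = 0.59 with an estimated correlation), the same as when adjusted over the list alone, and the call was lost with quantile normalization (camera, adjusted p = 0.057). Calcium handling and ion channel genes rose in 15 of 25 cases and fell in 2 (median 0.51, camera, adjusted p = 0.00017, and adjusted p = 0.59 with an estimated correlation), with the same counts when adjusted over the list alone. Trdn, the triadin gene, was at 1.78 ± 0.12 (SE) and Pln, the phospholamban gene, at 0.57 ± 0.08. Cardiac transcription factor genes rose in 11 of 25 cases and fell in 4 (median 0.24, camera, adjusted p = 0.0073, and adjusted p = 0.59 with an estimated correlation), with the same counts when adjusted over the list alone. Irx3 was at 1.79 ± 0.08 and Hopx at 1.60 ± 0.17. In the sarcomere list 15 of 23 rose and 4 fell (median 0.48, camera, adjusted p = 0.00015, and adjusted p = 0.59 with an estimated correlation), or 15 and 5 when adjusted over the list alone. Of 14 working cardiomyocyte markers 10 rose and 3 fell (median 0.57, camera, adjusted p = 0.00054, and adjusted p = 0.59 with an estimated correlation), or 11 and 3 when adjusted over the list alone. The myosin heavy chain genes parted: Myh6, the adult rodent ventricular form, went from 2431 ± 341 to 5514 ± 683 FPKM and Myh7, the fetal form, from 2306 ± 206 to 872 ± 68.1. Tnni3, the adult troponin I gene, rose 2.34-fold from 1760 ± 81.4 to 4115 ± 617 and the atrial light chain gene Myl7 4.18-fold from 68.3 ± 11.8 to 285 ± 65.3. Of 13 fetal and stress genes 8 fell and 3 rose, with Nppb down from 2838 ± 74.6 to 1112 ± 103, a list just outside the threshold (median -0.35, camera, adjusted p = 0.0504), and 9 fell and 3 rose when adjusted over the list alone. It passed with quantile normalization (median -0.61, camera, adjusted p = 0.0036), a pseudocount of 0.1 (0.047) and only the 6 libraries (0.046), and without control library 1 (0.030) or 2 (0.047) or Yap library 2 (0.037).

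**Figure D3:**
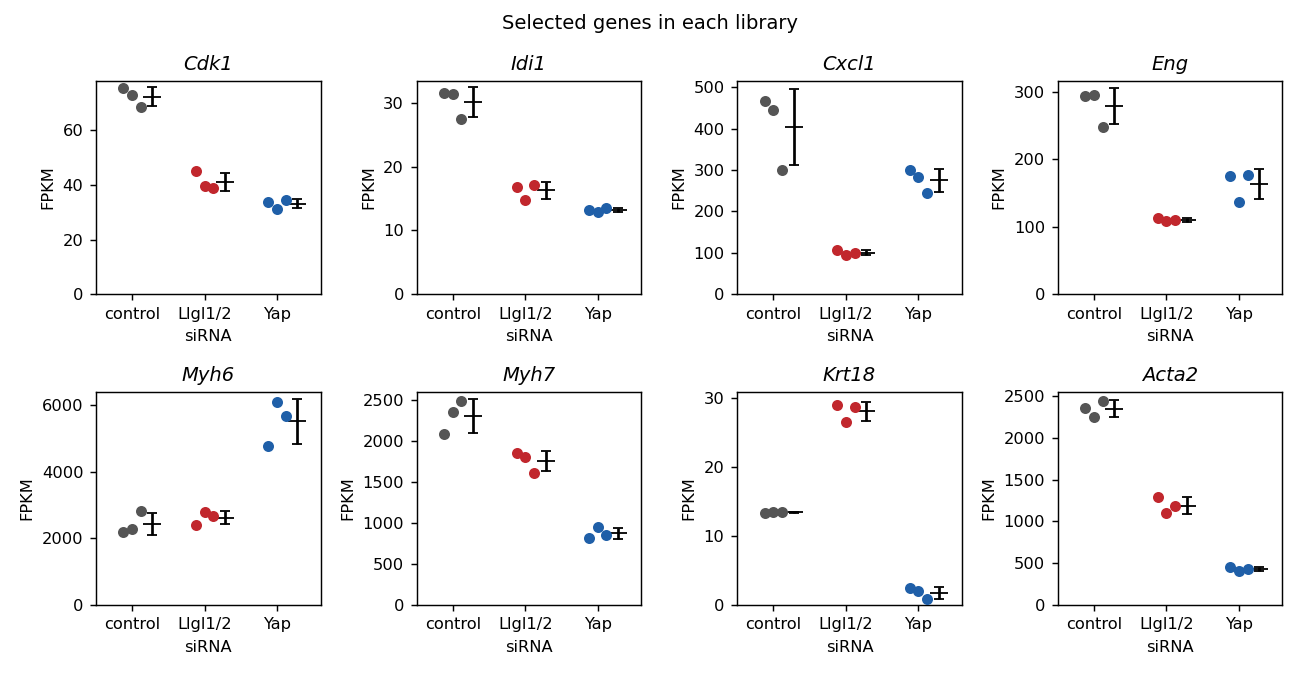
FPKM of 8 named genes in each of the 9 libraries, with each group's mean and SD (n = 3) as a bar beside the points. Myh6 averaged 5514 FPKM after Yap siRNA against 2431 in the controls, Cxcl1 100 after Llgl1/2 siRNA against 404, and Krt18 28.1 after Llgl1/2 siRNA, 13.4 in the controls and 1.71 after Yap siRNA.

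Inflammatory genes also fell after Yap siRNA. In the NF-kB list 21 of 25 fell and none rose (median log2 change -0.50, camera, adjusted p = 9.2e-05, and adjusted p = 0.59 with an estimated correlation), also 21 when adjusted over the list alone. Ptgs2, the inducible cyclooxygenase gene, was at -0.88 ± 0.11 (SE) and Icam1, a leukocyte adhesion gene, at -0.74 ± 0.09. Interferon-stimulated genes fell in 17 of 27 cases and rose in 1 (median -0.40, camera, adjusted p = 0.00026, and adjusted p = 0.59 with an estimated correlation), with the same counts when adjusted over the list alone. Cxcl10 was at -1.32 ± 0.11. Beside them, endothelial markers fell in 7 of 14 cases and rose in 1 (median -0.31, camera, adjusted p = 0.028, and adjusted p = 0.59 with an estimated correlation), or 8 and 1 when adjusted over the list alone. Eng went from 279 ± 27.1 to 163 ± 22.2 FPKM (SD, n = 3) and Pecam1 from 88.5 ± 9.97 to 59.3 ± 7.60, and the list's call was lost without Yap library 3 (camera, adjusted p = 0.066) and with a filter at 10 FPKM (0.054). Leukocyte markers had 3 of 15 higher and 5 lower (camera, adjusted p = 0.65). Cd74 was at 0.96 ± 0.16 and Cd14 at -0.72 ± 0.15. Fibroblast markers had 5 of 13 higher and 1 lower (camera, adjusted p = 0.19). Dcn went from 15.9 ± 2.91 to 33.3 ± 4.46 FPKM and Lum was at 0.65 ± 0.13, the other way from Llgl1/2 siRNA. Smooth muscle and pericyte markers had 6 of 13 higher and 5 lower (camera, adjusted p = 0.89). Abcc9 was at 1.65 ± 0.11 and Tagln at -1.23 ± 0.12. Epicardial markers had 1 of 7 higher and 3 lower (camera, adjusted p = 0.29), and erythroid markers 1 of 4 lower (adjusted p = 0.29). Adjusted over the list alone these 5 lists had the same counts, except that no erythroid marker passed.

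The other lists did not pass camera's threshold after Yap siRNA. Extracellular matrix genes had 3 of 22 higher and 8 lower (camera, adjusted p = 0.23), immediate early genes 1 of 22 higher and 10 lower (adjusted p = 0.14, and 0.049 without Yap library 1), apoptosis regulators 2 of 24 higher and 8 lower (adjusted p = 0.23) and growth factor genes 4 of 22 higher and 11 lower (adjusted p = 0.26). Notch genes had 1 of 10 higher and 3 lower (camera, adjusted p = 0.26), junction genes 4 of 18 higher and 9 lower (adjusted p = 0.29), unfolded protein and integrated stress response genes 7 of 24 higher and 8 lower (adjusted p = 0.44) and Wnt targets 5 of 13 higher and 4 lower (adjusted p = 0.47). Apicobasal polarity genes had 3 of 18 higher and 6 lower (camera, adjusted p = 0.56), planar cell polarity genes 2 of 15 higher and 4 lower (adjusted p = 0.65), p53 targets 5 of 22 higher and 5 lower (adjusted p = 0.79) and antioxidant genes 5 of 25 higher and 9 lower (adjusted p = 0.87). Glycolysis genes had 7 of 22 higher and 6 lower, with a median of -0.09 against a mean of 0.05 and a test toward higher values (camera, adjusted p = 0.70), and hypoxia genes 5 of 18 higher and 7 lower, with a median of -0.04 and a mean of -0.03 against a test toward higher values (adjusted p = 0.93). The smooth muscle list, too, had a median of 0.11 and a mean of -0.02. Adjusted over the list alone, the counts in this paragraph differed by at most 2 genes in either direction. Individual members moved strongly in lists without a call: Vegfa, the vascular growth factor gene, rose by 0.84 ± 0.06 (SE), the gap junction gene Gja1 rose from 173 ± 4.33 to 329 ± 9.42 FPKM (SD, n = 3), and Asns, the asparagine synthetase gene, fell by 1.01 ± 0.08. In total 16 of 36 lists passed, 6 higher and 10 lower, and none passed with an estimated correlation.

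The direct comparison of both knockdowns asked where their effects differ. Genes of NF-kB inflammation and endothelial markers were lower after Llgl1/2 siRNA than after Yap siRNA, and DNA replication genes were higher, at camera's preset correlation but not with an estimated correlation (adjusted p = 0.67). Krt18 was at 28.1 ± 1.40 FPKM (SD, n = 3) after Llgl1/2 siRNA and 1.71 ± 0.821 after Yap siRNA, and Cdh3, the placental cadherin gene, at 11.9 ± 1.12 and 1.33 ± 0.314. Gstm2, a glutathione transferase gene, was at 106 ± 3.94 and 16.5 ± 0.745 and Ccl20 at 26.2 ± 2.14 and 3.92 ± 1.93. In the other direction Pla2g2a was at 7.72 ± 0.642 and 108 ± 15.5, Reg3b at 19.1 ± 3.10 and 168 ± 27.4, Cxcl6 at 9.25 ± 2.23 and 71.3 ± 7.19 and Serpinb2, a plasminogen activator inhibitor gene, at 3.59 ± 0.781 and 25.9 ± 5.38. Yap1 itself was higher by 3.05 ± 0.11 (SE), Rpl37a by 2.64 ± 0.27, and Rn5s lower at -2.59 ± 0.37, both uncertain as above. Of 10789 genes 5070 passed limma's threshold, 3024 higher and 2046 lower after Llgl1/2 siRNA, and 161 and 194 of these differed by at least 1 on the log2 scale. With median-ratio scaling of the FPKM values, chosen after seeing the data, the split was 2357 higher and 2569 lower, so the surplus of higher genes depends on the scaling. Llgl1 was lower than after Yap siRNA by -0.77 ± 0.11 (limma, adjusted p = 0.00010) and Llgl2 by -0.36 ± 0.13 (limma, adjusted p = 0.036). The Llgl2 call was lost in 5 settings, among them the fit without Yap library 3 (-0.21, limma, adjusted p = 0.16).

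In this comparison 12 of 36 lists passed camera's threshold, 6 higher and 6 lower, and none with an estimated correlation. After Llgl1/2 siRNA 19 of 25 NF-kB genes were lower and 1, Ccl20, was higher than after Yap siRNA (median log2 difference -0.65, camera, adjusted p = 4.5e-09, and adjusted p = 0.67 with an estimated correlation), or 22 and 1 when adjusted over the list alone. Beside them 11 of 14 endothelial markers were lower (median -0.45, camera, adjusted p = 1.6e-06, and adjusted p = 0.67 with an estimated correlation), or 12 when adjusted over the list alone. Interferon-stimulated genes were lower in 15 of 27 cases and higher in 2 (median -0.29, camera, adjusted p = 0.0013, and adjusted p = 0.67 with an estimated correlation), or 16 and 2 when adjusted over the list alone. Fibroblast markers were lower in 5 of 13 cases and higher in 1, leukocyte markers lower in 5 of 15 and higher in none, both with the same counts when adjusted over the list alone (camera, adjusted p = 0.025 for each, and adjusted p = 0.67 with an estimated correlation for each). G1/S and DNA replication genes were higher in 16 of 25 cases and lower in none (median 0.47, camera, adjusted p = 0.0013, and adjusted p = 0.67 with an estimated correlation), with the same count when adjusted over the list alone. Fetal and stress genes of the myocyte were higher in 9 of 13 cases and lower in 2 (median 0.55, camera, adjusted p = 0.025, and adjusted p = 0.67 with an estimated correlation), with the same counts when adjusted over the list alone. Junction genes were higher in 11 of 18 cases and lower in 3 (camera, adjusted p = 0.034, and adjusted p = 0.67 with an estimated correlation), or 12 and 3 when adjusted over the list alone. With a camera adjusted p of 0.041 each (adjusted p = 0.67 with an estimated correlation), focal adhesion and SRF/MRTF genes were higher in 14 of 26 cases and lower in 4, p53 targets higher in 10 of 22 and lower in 1, apicobasal polarity genes higher in 9 of 18 and lower in none, and stress response genes lower in 8 of 24 and higher in 4. Adjusted over the list alone these 4 lists had the same counts, except for 15 higher focal adhesion genes. Several of these calls are unstable. With the fry test in limma interferon-stimulated genes (adjusted p = 0.075) and leukocyte markers (adjusted p = 0.11) did not pass. Apicobasal polarity was lost with quantile normalization (camera, adjusted p = 0.061), a filter at 10 FPKM (0.22) or replicate number as a factor (0.053). It was also lost without Llgl1/2 library 2 (0.057) or 3 (0.057) or Yap library 1 (0.061) or 3 (0.054). The stress response call was lost with quantile normalization (camera, adjusted p = 0.11), the 10 FPKM filter (0.077), and without the same 4 libraries (0.074, 0.057, 0.061 and 0.058). The p53 call was lost with quantile normalization (camera, adjusted p = 0.056), the 10 FPKM filter (0.077), and without Llgl1/2 library 1 (0.051) or 3 (0.057) or Yap library 3 (0.054). Focal adhesion was lost without Llgl1/2 library 1 (camera, adjusted p = 0.051) or Yap library 2 (0.076), leukocyte markers with the 10 FPKM filter (0.077) and without Llgl1/2 library 3 (0.071) or Yap library 1 (0.071), and fibroblast markers with the 10 FPKM filter (0.35). YAP/TAZ targets had 9 of 19 higher and 5 lower. The difference in that list between both knockdowns did not pass camera (adjusted p = 0.12) but passed fry (adjusted p = 0.0011). Calls were also gained. With fry 21 of 36 lists passed, among them also planar cell polarity (fry, adjusted p = 0.0011), Wnt targets (0.0011) and Hippo genes (0.0017). Planar cell polarity genes, 6 of 15 higher and none lower (camera, adjusted p = 0.053), passed with median-ratio scaling (0.038), the 10 FPKM filter (0.026), and without Llgl1/2 library 2 (0.046) or Yap library 3 (0.040). Hippo genes, 10 of 23 higher and 1 lower (camera, adjusted p = 0.067), passed with the 10 FPKM filter (0.046) and without Llgl1/2 library 1 (0.025) or Yap library 2 (0.048). Extracellular matrix genes, 5 of 22 higher and 9 lower (camera, adjusted p = 0.075), passed without Llgl1/2 library 1 (0.037) or Yap library 2 (0.048), and fatty acid oxidation genes, 5 of 29 higher and 12 lower (0.075), without Yap library 1 (0.045). Oxidative phosphorylation and apoptosis lists had medians of 0.05 each against a test toward lower values (camera, adjusted p = 0.79 and 0.78).

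Both knockdowns were then set side by side over the genes called in each. Of the 4338 and 5181 genes, 2500 were called in both, 1091 higher in both, 1084 lower in both and 325 in opposite directions, so 87.0% of the genes called in both moved the same way. Over all tested genes 66.3% had the same sign, against 68.9% (SD 9.29) in simulations of unchanged groups with shared controls. Genes called in both and higher included Igfbp5, Sphkap, Cygb, Cpt1b and Dkk3, and those lower in both included Cdk1, Rrm2, Ccnd1, Itgb1 and Idi1. Of the 325 genes, 214, among them Krt18 and Ccl20, were higher after Llgl1/2 siRNA and lower after Yap siRNA, and 111, among them Dcn and Lum, were the reverse. Independent lists of these sizes would share 489 higher, 538 lower and 1056 opposite genes. Both comparisons use the same 3 control libraries, and 100 simulations of unchanged groups against shared controls gave a mean overlap of 0.01 genes. Independent lists leave out the shared controls, and the simulations leave out the effects. With 3 controls, too few to split, part of the excess may come from the shared controls. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.48, against 0.54 (SD 0.22) in the simulations. Shared controls alone raise r and the share of same signs, so neither measures a shared response here. The covariance of the log2 changes was 0.0938 against 0.0105 in the simulations, a difference of 0.0833. The simulations cover only the spread between control libraries. A shift common to all 3 controls would stay in that difference.

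**Figure D4:**
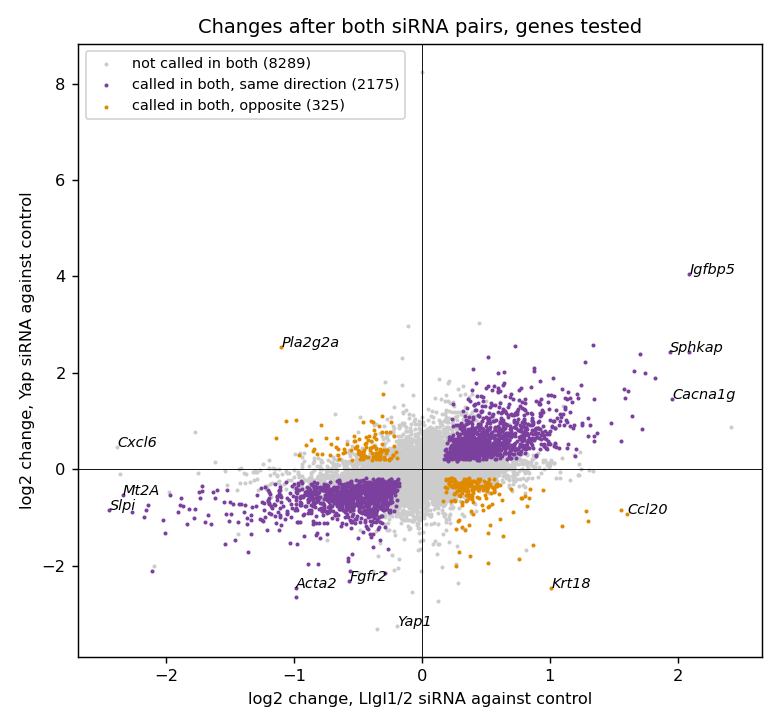
Log2 change of each tested gene after Llgl1/2 siRNA (horizontal axis) and after Yap siRNA (vertical axis) against the same 3 control libraries, on the log2(FPKM + 1) scale, with named genes labelled. Across the 10789 genes r was 0.48, against a mean of 0.54 in simulations of unchanged groups with shared controls. Shared controls alone raise r, so these 2 values do not measure a shared response. The covariance was 0.0938, against 0.0105 in the simulations.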

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

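Of 5747 results under alternatives, 5633 kept their direction and side of the threshold, 80 lost a call, 24 gained 1, 10 counts moved and 0 genes or lists reversed, but the balance of higher and lower genes did not hold. This tally overstates stability. Of its results 4150 were values of named genes, most of them picked for a large change or a small p. Lists that lost their call with an estimated correlation or fry entered only as counts of lists, not among the 80. Leaving out 1 library gave 3315 to 4043 genes for Llgl1/2 siRNA, 4342 to 4974 for Yap siRNA, 4176 to 4939 for the direct comparison and an overlap of 1757 to 2488, with r from 0.44 to 0.53. An adjusted p of 0.01 left 2801 genes for Llgl1/2 siRNA and an overlap of 1418, and a log2 change of at least 1 left 260, 447 and 355 genes in the 3 comparisons, both by a stricter threshold. With an estimated correlation 0, 0 and 0 lists passed camera, and fry passed 27, 29 and 21 lists. In the direct comparison fry kept 10 of the 12 lists. Median-ratio scaling, chosen after seeing the data, moved the share of higher genes from 54.9% to 49.3% for Llgl1/2 siRNA, from 42.8% to 49.2% for Yap siRNA and from 59.6% to 47.8% in the direct comparison, and the cause was not tested. In that comparison Llgl2 missed limma's threshold at an unchanged -0.36 with no filter (adjusted p = 0.061) and with only the 6 libraries (adjusted p = 0.051). It also missed it without Llgl1/2 library 1 (-0.31, limma, adjusted p = 0.12), Llgl1/2 library 2 (-0.38, adjusted p = 0.066) or Yap library 3 (-0.21, adjusted p = 0.16). It was at -0.46 without Yap library 1, and the cause was not tested. Named genes that lost their call in some setting were Notch3, Wt1, Dpt, Tbx18, Hbb and Hes1 after Yap siRNA, and Pard3b, Hey2 and Notch1 after Llgl1/2 siRNA. FPKM values carry no read totals, so depth could not be weighed, and tests that need counts were not run.

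Replicate number as a block gave 4721, 5558 and 5452 genes, 19, 15 and 11 lists and an overlap of 2844. Deviations from group means correlated at 0.01 to 0.24 between libraries of the same number, 5 of 9 pairs were over 0.1, among them all 3 between Llgl1/2 and Yap siRNA, and 6 of 9 libraries correlated best with their own number. That is a hint of shared sets, but the labels name none and the other 4 pairs were not over 0.1, so the single fit was kept without the block and the question stays open. The block ended 2 list calls (Hippo after Yap siRNA, camera, adjusted p = 0.052, and apicobasal polarity in the direct comparison, camera, adjusted p = 0.053) and added Hbb-b1 after Llgl1/2 siRNA.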

Other observations

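Gene ontology process terms, chosen for testing after the list results were seen, add groups that the fixed lists do not cover, and the genes named here were picked after their values were seen. The deposited term assignments are loose (ribosomal protein genes appear under pancreas development), so terms of that kind are left undescribed, though the totals below count them. Genes of ribosome biogenesis fell after Llgl1/2 siRNA in 18 of 63 cases and rose in 3 (median log2 change -0.18, camera, adjusted p = 0.0095, and adjusted p = 0.97 with an estimated correlation), with the processing factor genes Utp18 at -0.66 ± 0.11 (SE) and Rrp9 at -0.52 ± 0.11 and the nucleolar methyltransferase gene Fbl at -0.48 ± 0.12. Genes of protein N-linked glycosylation fell in 16 of 50 cases and rose in 2 (median -0.16, camera, adjusted p = 0.027, and adjusted p = 0.97 with an estimated correlation). Gfpt2 and Uap1, which make the sugar donor, were at -1.16 ± 0.12 and -0.77 ± 0.09. Dicarboxylic acid metabolism genes rose in 16 of 27 cases and fell in 1 (median 0.24, camera, adjusted p = 0.0057, and adjusted p = 0.97 with an estimated correlation), with Aldh5a1 at 0.93 ± 0.10 and the isocitrate dehydrogenase gene Idh2 at 0.44 ± 0.09. After Yap siRNA RNA transport genes fell in 17 of 29 cases and rose in none (median -0.35, camera, adjusted p = 0.012, and adjusted p = 0.98 with an estimated correlation), with the nuclear pore genes Ndc1 at -1.02 ± 0.13 and Nup155 at -0.69 ± 0.10 and Ran, the transport GTPase gene, at -0.74 ± 0.11. Of 381 terms 27 passed camera after Llgl1/2 siRNA, 3 after Yap siRNA and 6 in the direct comparison, and 0 passed with an estimated correlation.

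The tests in this and the next 3 paragraphs were chosen after the results were seen. The 6 libraries of each comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 4338 genes for Llgl1/2 siRNA, 5181 for Yap siRNA and 5070 in the direct comparison, the highest other split gave 1 in each, and so only the real split, 1 of 10, reached its own count. Each other split mixes libraries of both groups, so a real difference would widen the spread within its groups. Its low count therefore does not show how many calls chance gives.

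Myl6l was above 0 after Yap siRNA alone, while Myl6 fell by 0.42. If reads moved between these near-copies, their sum should stay level. The sum was 1209 ± 9.08 FPKM (SD, n = 3) after Yap siRNA and 1167 ± 41.2 in the controls, a log2 ratio of 0.05, and it was 1292 ± 127 after Llgl1/2 siRNA. Moved reads could account for the rise of Myl6l, and a change of the gene itself was not tested.

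Lower inflammatory genes may reflect the siRNAs, a response raised in the control libraries, or fewer cells of another type. After Llgl1/2 siRNA 19 of 25 NF-kB genes were also below Yap siRNA. A response raised in the control libraries alone does not give that difference. There is no untransfected group, so a response raised unequally in the control and Yap siRNA libraries cannot be told apart from a lowered response. The same holds for a difference in siRNA load. For Yap siRNA, with a median of -0.50, a raised control cannot be told apart from a lowered response either. Leukocyte markers fell less than NF-kB genes (difference of medians 0.70, permutation p = 0.00481 over genes), so an even loss of leukocytes is not the whole cause. The marker list is mixed, and a loss of only some leukocytes was not tested. Endothelial markers fell nearly as far (difference 0.11, permutation p = 0.352), so fewer endothelial cells cannot be told apart from a lowered response, although 9 of 25 NF-kB genes, Cxcl6 (-2.38) and Nos2 (-2.16) among them, lay over 2 standard errors below the lowest endothelial marker (-1.37). Permutations treat genes as independent, which they are not.

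Higher sarcomere and mitochondrial genes may reflect a program in the myocytes, a higher share of myocytes, or a gain in short transcripts. A higher share through an equal loss of all other cells should lower the markers of 6 other cell types (65 genes) alike. After Llgl1/2 siRNA their medians spanned 1.31 (permutation p = 0.00202), from -1.04 for endothelial to 0.27 for smooth muscle and pericyte markers. An equal loss of the other cells alone would not give such a spread, unless marker genes also changed within cells. The permutations in this paragraph treat genes as independent, which they are not. An unequal loss would also raise the share of myocytes, so a higher share cannot be told apart there. After Yap siRNA 4 of 23 sarcomere genes fell (Myh7, Actc1, Csrp3 and Actn2), so a higher share is not the whole cause of the sarcomere changes. For mitochondrial genes after Yap siRNA a higher share cannot be told apart, since the other types' medians spanned 0.64 (permutation p = 0.225). Among 2 pairs of lists also tried fibroblast minus endothelial gave 0.41 (permutation p = 0.00187) and smooth muscle minus endothelial 0.48 (permutation p = 0.0136). These differences bear only on an equal loss. The 81 ribosomal protein genes, which have short transcripts, lay -0.33 from the oxidative phosphorylation and -0.45 from the sarcomere genes after Llgl1/2 siRNA (permutation p = 1e-05 for each, the smallest the permutations can give), so short transcripts are not the whole cause. After Yap siRNA they lay -0.28 from the sarcomere genes (permutation p = 0.015), so short transcripts are not the whole cause of the sarcomere changes. From the oxidative phosphorylation genes the difference was 0.0333 (permutation p = 0.785), and with quantile normalization the medians were 0.02 and 0.10, so for mitochondrial genes that cause stays open.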
